A study of Rattus norvegicus with 12 samples.

How the data were processed

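PolyA-selected, stranded RNA libraries (NEBNext Ultra Directional kit) were sequenced on an Illumina NovaSeq with paired 150-bp reads, from 12 samples of iAM-1 cells in 4 groups of 3. The cells were differentiated in 2% serum without doxycycline, and the lentiviral shRNA vectors were added shortly after differentiation had begun. The groups were untransduced cells, cells with the control shRNA ppluc and cells with either of 2 shRNAs against Sbk2. The titles of both Sbk2 groups begin with the number 11, and their names tell shRNA 1 from shRNA 2. The target sequence of either shRNA is not given in the sources used here.

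The deposited CPM values, read counts scaled to the library total, cover 32761 features and were averaged by the authors over the libraries of each group. The deposited TPM values, scaled also by transcript length, were averaged by the authors in the same way, with 43 identifiers placed on several loci. The deposited locus table gives the chromosome, start and end of each feature in Rnor_6.0, with starts counted from 0, to which 1 was added here. The processing notes name Rnor_6.0 and DESeq2 without saying what DESeq2 was used for, and the aligner, the counting tool and the handling of shared reads are not given in the sources used here. No column holds a single library.

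Single libraries were recovered from the averages by arithmetic. A deposited mean is the sum of 3 CPM values divided by 3 in double precision, and a CPM value is a whole number of reads over the library total, so that few triples of whole reads give the stored digits. The 3 totals of a group were found as whole numbers from its 3 most frequent values above 0, each taken as 1 read in 1 library. Triples of whole reads near each stored mean were then listed with a lattice reduction. They were kept if they return the mean to the last bit, with library CPM taken at 15 significant digits. For 2 or 3 features per group the only near triple was kept without returning the mean exactly. Exactly 1 triple was found for 99.8 to 99.9% of features per group, and of 2000 low values per group 1999 to 2000 were returned exactly. Of 3000 control values per group, shifted by 1e-10 of their size, 0 had any triple. On simulated libraries the single triples were right in 100.0% of cases. Features with several triples, 2 to 34 per group after those outside the usual spread were dropped (the 99th percentile of the spread above 100 CPM), are abundant genes such as Nppa, Myh6, Actc1 and Myl4. They were given their widest triple, and no error is printed for Myh6 and Myl4. These settings were chosen after the values were seen, while the gene lists, comparisons, tests and the rule for named genes were fixed before the data were examined. The letters of the libraries order them by total and carry no pairing. Group means printed as levels are the authors' own, while all tests rest on the recovered libraries. Pairs of libraries of a group correlated at 0.994 to 0.997 on the log2 scale.

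Library totals ran from 30274847 to 47517427 assigned reads, so that the floor of 3 reads is 0.0631 to 0.0991 CPM. Genes with at least 0.5 CPM in at least 3 of the libraries were kept, 12493 in all, and log2(CPM + 0.5) was fitted with limma 3.58.1 (lmFit, contrasts, eBayes with a trend) in R 4.3.3, with 1 mean per group. The 5 comparisons were both Sbk2 shRNAs as their mean, shRNA 1 and shRNA 2, each against ppluc, shRNA 1 against shRNA 2, and ppluc against untransduced. Calls use a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. On simulated libraries with a dispersion of 0.02 and 200 changed genes, this test recovered 100.0% of changes of 2 (log2), 85.1 to 98.5% of changes of 1 and 10.6 to 16.7% of changes of 0.5, with 2 or 3 false calls. The recovered libraries had a median standard error of 0.078 in comparisons of 2 groups and many more called genes. The simulated shares therefore do not tell what the test missed there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

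The rule named, per comparison, the Sbk genes, the 10 largest rises and falls among called genes with a symbol whose libraries did not overlap and whose higher side reached 1 CPM, and up to 4 members with the smallest p of each list. The text prints part of them. Genes beside these on chromosomes 7 and 10, and the transgenes, were chosen after their values were seen.

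Gene lists were written from general knowledge: sarcomere, calcium handling, ion channels and conduction, atrial identity, ventricular identity, cardiac transcription factors, intercalated disc and costamere, actin cytoskeleton and SRF targets, YAP and TGF-beta targets, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cell cycle, p53 targets, interferon response, NF-kB and inflammation, unfolded protein response, integrated stress response, heat shock and chaperones, muscle protein degradation, cholesterol synthesis, ribosomal proteins, extracellular matrix, small RNA machinery, and markers of fibroblasts, smooth muscle, endothelium, epicardium, immune cells and neural or glial cells. With the Sbk family they held 643 distinct symbols, of which 621 were matched, 9 through an older symbol, and the others, Ttn, Col1a2 and Pecam1 among them, were not analysed here. Some genes are in several lists, for example Acta2, Tagln and Cnn1 in those of smooth muscle and actin. Each of the 31 lists was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry. Members were called over all genes and over the list alone.

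The overlap of both shRNAs was set against independent lists, against 50 simulations of unchanged groups with shared controls, and against unshared controls. Runs of 5 neighbouring genes were compared with 1000 shuffles of all genes along the chromosomes. Alternatives were other pseudocounts, low-value filters, trimmed-mean and median-of-ratios scaling of the CPM values, robust eBayes and only the groups compared. Others were a 2-fold minimum, other control groups, each library left out and TPM group means. The TPM means carry no test and were used for the level of Sbk2 and the direction of named genes. Chosen after seeing the data were untransduced cells as the control of single genes, voom weights, array weights and other treatments of features with several triples. A ratio on few reads carries an exact interval that conditions on the sum of reads. Raw reads, isoforms and splice junctions were not analysed here.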

Results

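RNA was sequenced from iAM-1 cells, a line of conditionally immortalized atrial myocytes from newborn Wistar rats that carries a gene for the LT-tsA58 form of the SV40 large T antigen. The series asked how the transcriptome of differentiated iAM-1 cells changed when Sbk2, a gene of the SH3-binding kinase family, was knocked down with lentiviral shRNAs. The 12 samples formed 4 groups of 3: untransduced cells, cells given a vector with the control shRNA ppluc, and cells given either of 2 shRNAs against Sbk2, here shRNA 1 and shRNA 2. The titles carry the marks D9 and P10, which the labels do not expand.

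The deposited values were averages over the 3 libraries of each group, and the libraries were recovered from them. The reads assigned to features were 30880786, 34919366 and 35082868 in the untransduced libraries and 38321704, 38944015 and 47517427 with ppluc. They were 30274847, 32939830 and 40622056 with shRNA 1 and 30613250, 32281379 and 36734685 with shRNA 2. In such a library 1 read was worth 0.0210 to 0.0330 CPM (counts scaled to the library total). The first principal component held 66.8% of the variance and ordered the groups. Untransduced libraries lay at -47.9 to -47.3, ppluc at -38.2 to -36.5, shRNA 1 at 2.98 to 3.20 and shRNA 2 at 75.7 to 86.5. The second, with 21.1%, placed the shRNA 1 libraries at 45.8 to 48.8 and all others at -26.9 to -2.04. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measured only the spread between these samples, and how much of it is technical is not given in the sources used here. Group levels are the authors' means in CPM, log2 fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes, and ± gives the limma standard error from the 12 libraries.

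Sbk2, on chromosome 1 from 72425707 to 72433488 in Rnor_6.0, was low in every library given an shRNA against it. It stood at 45.2 CPM in untransduced cells, 27.1 with ppluc, 1.07 with shRNA 1 and 0.673 with shRNA 2. Single ppluc libraries lay between 24.8 and 29.6 CPM, from 967 to 1276 reads. The shRNA 1 libraries lay between 1.00 and 1.13 CPM (33 to 46 reads), and the shRNA 2 libraries between 0.620 and 0.719 CPM (20 to 25 reads). Against ppluc, Sbk2 changed by -4.13 ± 0.10 with shRNA 1 and by -4.55 ± 0.10 with shRNA 2 (limma adjusted p = 9.1e-16 and 2.4e-17, lower in 3 of 3 libraries with each). The level with shRNA 1 was above that with shRNA 2 by 0.43 ± 0.10 (limma adjusted p = 0.00081, not passed with voom weights), in libraries holding 20 to 46 reads of it. Sbk2 also fell with the control vector, by 0.73 ± 0.10 against untransduced cells (limma adjusted p = 6.6e-06).

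Sbk3, the neighbouring family member from 72420352 to 72422974 on the same chromosome, followed the same order at lower levels, 7.07, 4.11, 2.69 and 1.17 CPM in untransduced, ppluc, shRNA 1 and shRNA 2 cells. Its change against ppluc was -0.54 ± 0.14 with shRNA 1 and -1.47 ± 0.14 with shRNA 2 (limma adjusted p = 0.0025 and 1.4e-08). Sbk1 had 0 to 3 reads per library and was not tested. The plot of Sbk2 and Sbk3 by group shows each library.

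**Figure D1:**
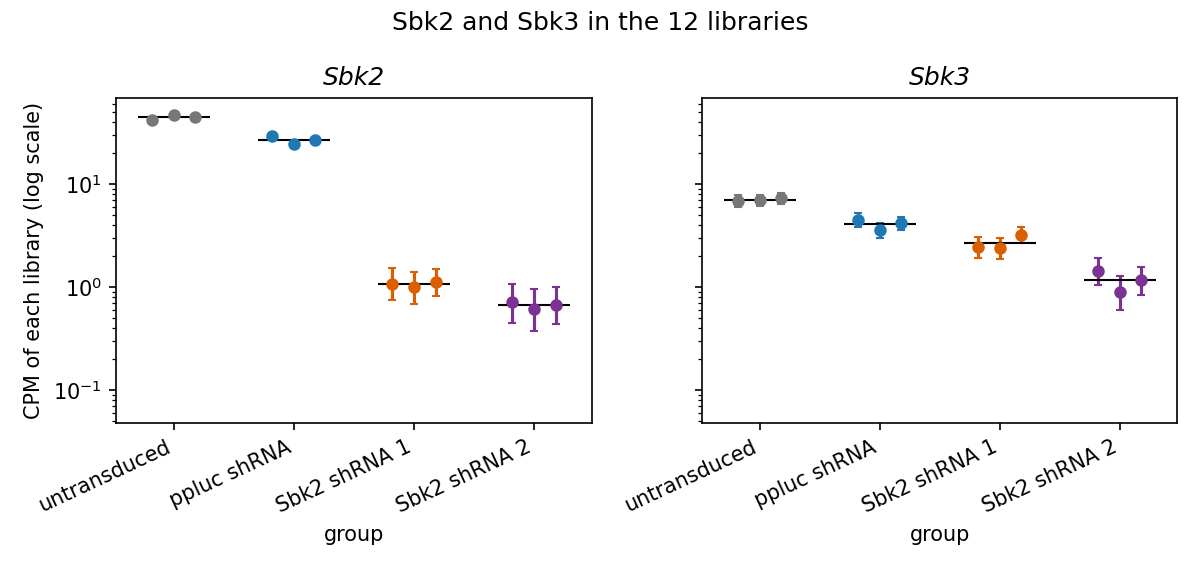
Level of Sbk2 (left) and Sbk3 (right) in each of the 12 libraries, in CPM on a log axis. Points are libraries, bars their exact Poisson 95% intervals, which cover counting error only, and lines the group means. Sbk2 lies at 24.8 CPM or above in the ppluc libraries and at 1.13 CPM or below in the 6 libraries with an shRNA against it.

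Cells given the control vector differed from untransduced cells in genes of the interferon and integrated stress responses, p53 targets and the matrix. They also differed in genes of oxidative phosphorylation and fatty acid oxidation. The vector's eGFP transcript went from 0.105 to 2417 CPM, and the end of the shRNA vector, with 0 reads in the 3 untransduced libraries, where 3 reads would be 0.0855 to 0.0971 CPM, stood at 602 CPM. Among the largest rises of endogenous genes were those of Tg, which encodes thyroglobulin (3.92 ± 0.14), Lrrc66 (3.71 ± 0.14), Mthfd2, an enzyme of mitochondrial one-carbon metabolism (3.03 ± 0.11), and Cdkn1c, a cyclin-dependent kinase inhibitor (2.40 ± 0.08, from 134 to 709 CPM). Art1 (-2.66 ± 0.17), Dhrs7c, a reductase of the sarcoplasmic reticulum (-2.47 ± 0.13), Mb, the gene of myoglobin (-2.36 ± 0.16), and Perm1, a regulator of muscle mitochondria (-2.22 ± 0.15), were among the largest falls. For each of these genes the 3 ppluc libraries lay all above or all below the 3 untransduced ones, as the rule for naming them required.

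Interferon-response genes rose with the control vector: 26 rose and 1 fell of 34 measured members (27 up and 0 down after trimmed-mean scaling, camera adjusted p = 8.2e-09, or 0.36 with an estimated correlation). Irf1, a transcription factor of that response, stood at 0.84 ± 0.06 and Oasl at 1.95 ± 0.14. Targets of p53 rose too (15 of 18, with 1 lower), among them Cdkn1a, the gene of the p21 cell cycle inhibitor (1.64 ± 0.09), and Tp53inp1 (1.10 ± 0.06; 16 up and 1 down after trimmed-mean scaling, camera adjusted p = 2.0e-08, or 0.11 with an estimated correlation). Of 18 genes of the integrated stress response 13 rose, among them Asns, asparagine synthetase (1.78 ± 0.11; 14 up and 0 down after trimmed-mean scaling, camera adjusted p = 4.0e-07, or 0.36 with an estimated correlation). Of 29 extracellular matrix genes 22 rose, with Loxl2 at 1.78 ± 0.05, and 3 fell, with Col8a1 at -2.14 ± 0.11 (22 up and 3 down after trimmed-mean scaling, camera adjusted p = 4.4e-07, or 0.36 with an estimated correlation). Actin cytoskeleton genes rose in 13 of 20 cases and fell in 5, with Tagln2 at 1.42 and Tmsb4x at -1.51 (13 up and 5 down after trimmed-mean scaling, camera adjusted p = 0.015, or 0.62 with an estimated correlation).

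Genes of oxidative phosphorylation and fatty acid oxidation were lower with the control vector. Glycolysis genes were not, with 7 up and 8 down of 20 and a median of 0.04 (9 up and 8 down after trimmed-mean scaling). Nuclear genes of oxidative phosphorylation fell in 27 of 30 cases, with a median of -0.28 and Cyc1 at -0.57 ± 0.06 (1 up and 23 down after trimmed-mean scaling, camera adjusted p = 3.2e-05, or 0.62 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 cases, with a median of -0.59 (0 up and 12 down after trimmed-mean scaling, camera adjusted p = 0.00058, or 0.57 with an estimated correlation). Fatty acid oxidation genes fell in 18 of 24 cases, with Hadh at -1.44 ± 0.06 (1 up and 17 down after trimmed-mean scaling, camera adjusted p = 0.00013, or 0.36 with an estimated correlation). Cardiac transcription factors fell in 9 of 14 cases, with Zfpm2 at -1.22 ± 0.07 (1 up and 9 down after trimmed-mean scaling, camera adjusted p = 0.028, or 0.63 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 22, with Hmgcs1 at -0.87 ± 0.06 (2 up and 9 down after trimmed-mean scaling, camera adjusted p = 0.046, or 0.62 with an estimated correlation). In limma over 12493 genes 7146 passed an adjusted p of 0.05, 3111 higher and 4035 lower, or 3622 and 3536 after trimmed-mean scaling and 3591 and 3561 after median-of-ratios scaling. As deposited, 533 of them changed by 2-fold or more. The libraries of both groups lay apart for 8046 genes (64.4%, where chance gives 10%). The other 21 of the 31 lists did not pass camera. Among them, sarcomere genes fell in 26 and rose in 9 of 42 cases, with a median of -0.26 (9 up and 23 down after trimmed-mean scaling). Ion channel genes fell in 10 and rose in 3 of 17 cases, with a median of -0.33. Ventricular genes fell in 4 and rose in 1 of 5 cases, and atrial genes split 6 up and 6 down of 18.

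With Sbk2 knocked down, the mean of both shRNAs against ppluc showed lower transcripts of the contractile and electrical machinery. Transcripts of cell division, the interferon response and the integrated stress response were higher. The lists of interferon response and integrated stress response passed camera with shRNA 2 and not with shRNA 1 alone. With an estimated correlation neither passed with shRNA 2 (adjusted p = 0.21 and 0.20). After Sbk2 itself (-4.34 ± 0.09), the largest falls included those of Sh3kbp1, an endocytic adaptor (-4.30 ± 0.10), Tmem72 (-3.60 ± 0.12), Cilp, an extracellular matrix protein gene (-3.50 ± 0.10) and Vil1, which encodes the actin binder villin (-3.37 ± 0.14). Hcn4, the gene of a pacemaker channel, went from 303 CPM to 82.6 with shRNA 1 and 10.3 with shRNA 2 (-3.35 ± 0.06). Mylk, a myosin light chain kinase gene (-3.34 ± 0.08), Ckm, the muscle creatine kinase gene (-3.26 ± 0.20), and Hrc, a calcium binder of the sarcoplasmic reticulum (-3.23 ± 0.09), fell as well. The largest rises included those of Rnd1 (4.06 ± 0.07, from 6.71 to 81.4 and 176 CPM), the interferon-induced Rsad2 (3.44 ± 0.22), Ctxn1 (3.41 ± 0.10) and Ulk4 (3.35 ± 0.15). Also high were the stress cytokine gene Gdf15 (3.24 ± 0.14), the stress-induced transcription factor gene Atf3 (3.22 ± 0.12) and Plat, tissue plasminogen activator (3.15 ± 0.08). As the rule for naming them required, each of these genes had all 6 knockdown libraries on one side of all 3 ppluc libraries.

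The limma test called 10394 of 12493 genes, 8050 higher and 2344 lower, of which 2143 changed by 2-fold or more. The median of all genes was itself shifted by 0.37, and by 0.26 and 0.50 with shRNA 1 and shRNA 2 alone. After trimmed-mean scaling, which takes that shift out, the split was 4848 higher and 4779 lower, and after median-of-ratios scaling 4811 and 4829. For the Sbk2 shRNAs, counts of list members and list medians are therefore given as deposited and, where marked as after scaling, after trimmed-mean scaling. Camera compares a list with the other genes and was run on the values as deposited only. It uses statistics that divide each change by its error, so the shift need not cancel in full.

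Of the 22 lists that passed camera on the mean, 22 also passed with shRNA 2 alone and 14 with shRNA 1 alone. None passed with an estimated correlation (smallest adjusted p = 0.096 for the mean, 0.12 for shRNA 2 and 0.095 for shRNA 1). The lists that passed with shRNA 2 and not with shRNA 1 are given here with their counts for shRNA 1. They were those of interferon response (17 up and 5 down of 34, or 11 and 12 after scaling), integrated stress response (7 up and 8 down of 18, or 4 and 8 after scaling), p53 targets (14 up and 3 down of 18, or 13 and 4 after scaling) and cardiac transcription factors (5 up and 5 down of 14, or 2 and 7 after scaling). So were those of the intercalated disc (8 up and 8 down of 25, or 4 and 17 after scaling, camera adjusted p = 0.0502), muscle protein degradation (8 up and 5 down of 21, or 5 and 12 after scaling), endothelial (2 up and 2 down of 6, or 0 and 2 after scaling) and fibroblast markers (2 up and 3 down of 6, or 1 and 3 after scaling). With shRNA 1 the matrix list (11 up and 12 down of 29, or 7 and 16 after scaling), the actin list (7 up and 8 down of 20, or 2 and 14 after scaling) and the atrial list (5 up and 8 down of 18, or 3 and 12 after scaling) passed camera, with adjusted p = 0.58, 0.58 and 0.37 at an estimated correlation.

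Sarcomere genes fell: 38 of 42 were lower and 3 higher, with a median of -1.01, or -1.40 after trimmed-mean scaling (1 up and 40 down after scaling, camera adjusted p = 1.4e-23, or 0.096 with an estimated correlation). Myh7, a cardiac myosin heavy chain (-3.17 ± 0.08), Myl7, the atrial regulatory light chain (-2.92 ± 0.08), Csrp3, a muscle LIM protein (-2.59 ± 0.07, or -1.03 against untransduced libraries), and Tnnc1, cardiac troponin C (-1.34 ± 0.04), had the smallest p of that list. How reads shared by near-identical genes, such as the myosin heavy chains, actins and Gbp genes, were counted is not given in the sources used here. Genes of ion channels and conduction fell in 14 of 17 cases, with a median of -1.03 or -1.42, led by Hcn4 and the potassium channel gene Kcnq1 (-2.08 ± 0.07; 2 up and 15 down after scaling, camera adjusted p = 8.9e-10, or 0.099 with an estimated correlation). Calcium handling genes fell in 16 of 24 cases and rose in 6, with a median of -0.34 or -0.72, and with Srl, sarcalumenin, at -1.89 ± 0.05 (3 up and 18 down after scaling, camera adjusted p = 1.8e-06, or 0.096 with an estimated correlation). Genes of the intercalated disc and costamere fell in 18 of 25 cases, with Xirp1 at -1.70 ± 0.06, while Dsc2, a desmosomal cadherin gene, rose by 1.31 ± 0.05 (3 up and 21 down after scaling, camera adjusted p = 7.8e-08, or 0.13 with an estimated correlation). Actin cytoskeleton genes fell in 13 of 20 cases and rose in 3, among the latter Tmsb4x, which the control vector had lowered from 259.7 to 90.9 CPM and which stayed below the untransduced level with both shRNAs (1.09 ± 0.06, but -0.42 against untransduced libraries; 2 up and 17 down after scaling, camera adjusted p = 8.8e-07, or 0.14 with an estimated correlation). The control vector had raised the actin list, 13 up and 5 down with a median of 0.42, and the list was not tested against untransduced libraries.

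Chamber identity genes fell in lists that share members with the sarcomere list, Myl7 among the atrial and Myh7 among the ventricular genes. Of 18 atrial genes 14 fell, with Myl4, the atrial essential light chain, at -1.88, and 3 rose, with the natriuretic peptide gene Nppb at 1.49 ± 0.05 (3 up and 15 down after scaling, camera adjusted p = 3.0e-07, or 0.099 with an estimated correlation). Ventricular genes fell in 4 of 5 measured cases, including Lbh (-1.08 ± 0.05; 0 up and 5 down after scaling, camera adjusted p = 0.00041, or 0.099 with an estimated correlation). Cardiac transcription factors fell in 7 of 14 cases and rose in 4, with Mef2a at -1.11 ± 0.04 and Tbx20 at -0.84 ± 0.04 (1 up and 12 down after scaling, camera adjusted p = 0.00052, or 0.29 with an estimated correlation). The small heat shock protein genes Hspb7 (-2.34 ± 0.05) and Hspb1 (-1.50 ± 0.05) led the heat shock and chaperone list, where 11 of 18 fell (3 up and 13 down after scaling, camera adjusted p = 3.1e-05, or 0.096 with an estimated correlation). In the list of muscle protein degradation 9 rose and 8 fell of 21, with a median of -0.02, or -0.40 after trimmed-mean scaling, where 5 rose and 15 fell (camera adjusted p = 0.042, or 0.13 with an estimated correlation). Trim55 stood at -0.89 ± 0.05 and the lysosomal protease gene Ctsl at 1.04 ± 0.04.

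Genes of energy metabolism fell as groups. Nuclear oxidative phosphorylation genes were lower in 25 of 30 cases, with a median of -0.37 or -0.76 after trimmed-mean scaling and with the complex I gene Ndufv1 at -0.90 ± 0.04 (0 up and 28 down after scaling, camera adjusted p = 7.2e-13, or 0.18 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13 cases, with Mt-nd5 at -0.90 ± 0.08 (0 up and 13 down after scaling, camera adjusted p = 2.8e-07, or 0.14 with an estimated correlation). Fatty acid oxidation genes fell in 15 of 24 cases and rose in 8, a split of 20 to 1 after trimmed-mean scaling (camera adjusted p = 3.6e-06, or 0.0997 with an estimated correlation). Decr1 stood at -1.53 ± 0.04 and the fatty acid binding protein gene Fabp3 at -1.35 ± 0.05. Glycolysis genes fell in 11 of 20 cases and rose in 6, with the muscle forms Eno3 at -2.63 ± 0.05 and Pgam2 at -2.38 ± 0.13 (2 up and 17 down after scaling, camera adjusted p = 2.1e-05, or 0.13 with an estimated correlation).

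Cell cycle genes rose in 28 of 30 cases, with a median of 1.01 or 0.70 after trimmed-mean scaling, among them the replication licensing gene Mcm3 (1.41 ± 0.07) and the mitotic kinesin gene Kif11 (2.22 ± 0.13; 26 up and 3 down after scaling, camera adjusted p = 0.0012, or 0.12 with an estimated correlation). The T antigen transgene drives division of these cells when it is on. As deposited it stood at 12.1 CPM in untransduced cells, 8.45 with ppluc, 9.08 with shRNA 1 and 19.2 with shRNA 2. Interferon-response genes rose in all 34 measured cases, and in 27 of them after trimmed-mean scaling, with Gbp2 at 2.18 ± 0.05 and the chemokine gene Cxcl10 at 2.14 ± 0.10 (camera adjusted p = 6.9e-05, or 0.29 with an estimated correlation). Targets of p53 rose in 16 of 18 cases, with Plk2 at 2.49 ± 0.04 and Mdm2, the ubiquitin ligase of p53, at 1.13 ± 0.04 (15 up and 2 down after scaling, camera adjusted p = 0.0013, or 0.13 with an estimated correlation). Genes of the integrated stress response rose in 16 of 18 cases, with Ddit3, which encodes CHOP, at 1.92 ± 0.06 (12 up and 3 down after scaling, camera adjusted p = 0.017, or 0.38 with an estimated correlation).

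Extracellular matrix genes fell in 17 of 29 cases and rose in 8, with Eln, elastin, at -2.91 ± 0.09, Col1a1 at -2.60 ± 0.09 and Col8a1 at 2.80 ± 0.09, or 0.67 against untransduced libraries (4 up and 22 down after scaling, camera adjusted p = 2.5e-06, or 0.17 with an estimated correlation). The control vector had itself raised this list, 22 up and 3 down with a median of 0.53. No list was tested for the Sbk2 shRNAs against untransduced libraries, so for a list as a whole a return toward the untransduced level was not told from a loss. Single genes were fitted against untransduced libraries, and these values are given for some of them. Among markers of other cell types, those of smooth muscle fell in 8 of 9 cases, with Cnn1 at -1.42 ± 0.10, or -0.03 and not passing against untransduced libraries (1 up and 8 down after scaling, camera adjusted p = 9.2e-06, or 0.14 with an estimated correlation). Fibroblast markers split 3 up and 3 down of 6, or 1 and 4 after trimmed-mean scaling, with Thy1 at 0.91 ± 0.14 (camera adjusted p = 0.044, or 0.18 with an estimated correlation). Endothelial markers split 1 up and 2 down of 6, with Flt1 at -1.17 ± 0.07 (against untransduced libraries 0.13, not passing) and Egfl7 at 1.37 ± 0.15 (1 up and 5 down after scaling, camera adjusted p = 0.020, or 0.12 with an estimated correlation).

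The remaining 9 lists did not pass camera. Ribosomal protein genes rose in 14 and fell in 3 of 22 cases, which turned to 3 and 16 after trimmed-mean scaling (camera adjusted p = 0.65). Unfolded protein response genes rose in 15 and fell in 2 of 18 cases (9 and 6 after scaling; camera adjusted p = 0.16). Cholesterol synthesis genes rose in 15 and fell in 3 of 22 (10 and 8 after scaling; camera adjusted p = 0.59). Targets of YAP and TGF-beta rose in 11 and fell in 4 of 18 cases, which turned to 7 and 8 after scaling (camera adjusted p = 0.67). NF-kB and inflammation genes rose in 9 and fell in 2 of 14 (7 up and 5 down after scaling, camera adjusted p = 0.92). Small RNA machinery genes rose in 6 and fell in 4 of 13 cases, 3 and 9 after scaling (camera adjusted p = 0.25). Epicardial markers rose in 2 and fell in 2 of 7 cases, 1 and 4 after scaling (camera adjusted p = 0.085). Immune markers rose in 3 of 3, with Cd14 at 2.67 ± 0.12 (2 up and 0 down after scaling, camera adjusted p = 0.46). Neural and glial markers rose in 3 and fell in 2 of 5 (3 up and 2 down after scaling, camera adjusted p = 0.46).

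Adjusted over the list alone, the counts of higher and lower members were equal to those over all genes for 29 of 31 lists, and 1 fewer member rose in the epicardial (1) and small RNA machinery (5) lists. No list passed camera with an estimated correlation in this or the other comparisons, the smallest adjusted p being 0.095 with an estimated correlation (9 lists here had an unadjusted p under 0.05, and fry called 30). The unadjusted counts were 6 with shRNA 1, 12 with shRNA 2, 5 between the shRNAs and 3 for the control vector, where fry called 21, 29, 30 and 21 lists. For the ribosomal, small RNA machinery and epicardial lists the median was above 0 while camera pointed down, because camera measures from the other genes, which were shifted up. The neural and glial list pointed down as well, with a median of 0.57, above that of all genes, and a mean of 0.13. The plot of list medians shows the single shRNAs beside the control vector.

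With shRNA 1 against ppluc, Rcvrn, the gene of the calcium sensor recoverin, showed the largest rise (5.24 ± 0.14). It had 2 reads in the 3 ppluc libraries and 1964 in those of shRNA 1, a ratio of 1180.1 with an exact 95% counting interval of 326 to 9751. Enkur, a gene of cilia and sperm flagella (3.75 ± 0.20), Rnd1 (3.51 ± 0.08), Gas7 (3.41 ± 0.10), the keratin gene Krt80 (3.34 ± 0.16), Creb5 (3.13 ± 0.14) and Flt4, the receptor VEGFR-3 (3.12 ± 0.15), rose as well. The largest falls after Sbk2 included those of Tmem72 (-3.57 ± 0.14), the receptor kinase gene Ephb1 (-3.52 ± 0.09), Aqp4, a water channel (-3.36 ± 0.11), Hrc (-3.11 ± 0.10), Mylk (-3.07 ± 0.09) and the integrin gene Itgb8 (-3.05 ± 0.06, or -1.51 against untransduced libraries).

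Nuclear oxidative phosphorylation genes fell in 27 of 30 cases with shRNA 1, 28 when adjusted over the list alone, with a median of -0.51 or -0.79 after trimmed-mean scaling (1 up and 29 down after scaling, camera adjusted p = 2.4e-14, or 0.30 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 cases, with Mt-co2 at -1.58 ± 0.12 (0 up and 13 down after scaling, camera adjusted p = 6.8e-09, or 0.24 with an estimated correlation). Sarcomere genes fell in 29 and rose in 7 of 42 cases, with Myl7 at -2.52 ± 0.09 and Tmod1 at -1.42 ± 0.05 (3 up and 35 down after scaling, camera adjusted p = 6.2e-10, or 0.27 with an estimated correlation). Calcium handling genes fell in 14 and rose in 3 of 24 cases (2 up and 20 down after scaling, camera adjusted p = 1.5e-06, or 0.095 with an estimated correlation). The ion channel genes fell in 10 and rose in 4 of 17, with Hcn4 at -1.87 ± 0.07, or -0.84 against untransduced libraries (4 up and 11 down after scaling, camera adjusted p = 9.7e-05, or 0.30 with an estimated correlation). Targets of YAP and TGF-beta rose in 14 of 18 cases, or 10 up and 3 down after trimmed-mean scaling, with the receptor gene Axl at 1.82 ± 0.06 and Ctgf at 1.77 ± 0.06 (camera adjusted p = 0.012, or 0.33 with an estimated correlation). Cell cycle genes rose in 23 of 30 cases, with Plk1 at 1.55 ± 0.14 (18 up and 2 down after scaling, camera adjusted p = 0.027, or 0.31 with an estimated correlation). The T antigen transgene, at 0.10 ± 0.10, did not pass (limma adjusted p = 0.39). Interferon-response genes split 17 up and 5 down of 34, or 11 and 12 after trimmed-mean scaling (camera adjusted p = 0.95). Integrated stress response genes split 7 up and 8 down of 18, with Atf3 at 2.38 ± 0.14 and Aldh1l2 at -1.86 ± 0.11, or -0.16 and not passing against untransduced libraries (4 up and 8 down after scaling, camera adjusted p = 0.21).

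In limma 9173 genes passed with shRNA 1, 6838 higher and 2335 lower, or 4157 and 4243 after trimmed-mean scaling and 4218 and 4212 after median-of-ratios scaling. As deposited, 1421 changed by 2-fold or more. The libraries lay apart for 9566 genes (76.6%, where chance gives 10%). Camera called 15 of the 31 lists.

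With shRNA 2 against ppluc, sarcomere, channel and matrix genes fell, and every measured member of the interferon and integrated stress response lists rose as deposited. Rsad2 went from 3.02 to 168 CPM (5.70 ± 0.25), Ttbk1, a tau tubulin kinase gene, from 0.156 to 26.1 CPM (5.33 ± 0.15), and the neuronal kinesin gene Kif5c from 1.69 to 67.2 CPM (4.94 ± 0.14). Gbp4, an interferon-induced GTPase (4.72 ± 0.13), Alox5, 5-lipoxygenase (4.67 ± 0.16), and Myc, the growth-regulating transcription factor (4.62 ± 0.15), rose as well. Sh3kbp1 (-6.31 ± 0.11), Selplg, a selectin ligand (-5.03 ± 0.08), Cilp (-4.91 ± 0.12), Hcn4 (-4.83 ± 0.07) and Rasd1 (-4.56 ± 0.08) fell, and so did Myh6, the cardiac alpha myosin heavy chain gene (-4.15, from 15059.9 to 852 CPM).

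Sarcomere genes fell in 39 of 42 cases with shRNA 2, with a median of -1.73 or -2.23 after trimmed-mean scaling and with the skeletal actin gene Acta1 at -3.26 ± 0.06 (0 up and 40 down after scaling, camera adjusted p = 1.3e-23, or 0.12 with an estimated correlation). Ion channel genes fell in 15 of 17 cases (2 up and 15 down after scaling, camera adjusted p = 3.0e-09, or 0.12 with an estimated correlation). Atrial genes fell in 14 of 18, with Gja5, the gene of connexin 40, at -3.84 ± 0.12 (2 up and 15 down after scaling, camera adjusted p = 9.8e-08, or 0.12 with an estimated correlation). Matrix genes fell in 21 and rose in 7 of 29 cases, with Nid1, nidogen, at -3.98 ± 0.10 (3 up and 23 down after scaling, camera adjusted p = 1.8e-07, or 0.16 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 19 and rose in 5 of 30 cases, with the muscle form Cox8b at -3.40 ± 0.19 (1 up and 28 down after scaling, camera adjusted p = 1.8e-07, or 0.31 with an estimated correlation). Mitochondrially encoded genes fell in 7 and rose in 2 of 13 cases, with a median of -0.27 or -0.78 after scaling (0 up and 11 down after scaling, camera adjusted p = 0.0058, or 0.40 with an estimated correlation).

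All 34 measured interferon-response genes rose with shRNA 2, also after trimmed-mean scaling (34), with a median of 1.79 or 1.29 (camera adjusted p = 3.5e-06, or 0.21 with an estimated correlation). The chemokine gene Cxcl10 stood at 3.72 ± 0.11 and the antigen transporter gene Tap1 at 1.87 ± 0.05. All 18 genes of the integrated stress response rose as deposited, with Trib3 at 3.69 ± 0.12 and Phgdh, the entry enzyme of serine synthesis, at 2.56 ± 0.07 (16 up and 1 down after trimmed-mean scaling, camera adjusted p = 0.00021, or 0.20 with an estimated correlation). Targets of p53 rose in 17 of 18 cases, with Plk2 at 3.44 ± 0.05 (17 up and 1 down after scaling, camera adjusted p = 0.00050, or 0.13 with an estimated correlation). Cell cycle genes rose in 29 of 30 cases, with Mcm3 at 2.51 ± 0.08 (24 up and 1 down after scaling, camera adjusted p = 0.0032, or 0.13 with an estimated correlation). The T antigen transgene rose by 1.14 ± 0.10 as deposited (limma adjusted p = 2.4e-09), where the median of all genes rose by 0.50.

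In limma 10760 genes passed with shRNA 2, 8125 higher and 2635 lower, or 5208 and 4897 after trimmed-mean scaling and 5131 and 4983 after median-of-ratios scaling. As deposited, 4077 changed by 2-fold or more. The libraries lay apart for 10644 genes (85.2%, where chance gives 10%). Camera called 23 of the 31 lists. One shRNA 2 library stood further from the other 2 of its group (chi-square per gene 20.0 at most, where pairs without it lay at 10.1 or below), and without it 10772 genes passed.

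Both shRNAs moved 6381 genes the same way, 5261 up and 1120 down, and 1729 in opposite directions. Hrc fell with shRNA 1 (-3.11 ± 0.10) and shRNA 2 (-3.35 ± 0.10), as did Myl7 (-2.52 ± 0.09 and -3.33 ± 0.09) and Mylk (-3.07 ± 0.09 and -3.61 ± 0.09). So did Csrp3 (-1.77 ± 0.08 and -3.40 ± 0.08, but -0.22 with shRNA 1 against untransduced libraries, since the control vector had raised it from 20.4 to 61.4 CPM) and Hspb7 (-1.54 ± 0.05 and -3.13 ± 0.05). Plk2 rose with both (1.54 ± 0.05 and 3.44 ± 0.05), as did Ddit3 (1.06 ± 0.07 and 2.77 ± 0.07) and Gbp2 (0.97 ± 0.06 and 3.40 ± 0.06). Independent lists of the same sizes would share 4447 higher and 492 lower genes. Both comparisons used the same ppluc libraries, and simulated unchanged groups against those libraries gave a correlation of fold changes of 0.50 across genes. The observed correlation was 0.47. The covariance was 0.291 against a simulated 0.00572, a difference of 0.285. With unshared controls, shRNA 1 against ppluc and shRNA 2 against untransduced libraries or the reverse, 6170 and 5856 genes moved the same way. Of the genes called the same way, 75.2% changed by more with shRNA 2. After trimmed-mean scaling 5255 genes moved the same way. The simulated groups shared 0.02 called genes on average, and 66.6% of all their genes had the same sign with both, where 71.1% was observed. They carried no shift of all genes, while the observed medians were 0.26 with shRNA 1 and 0.50 with shRNA 2. These shares of equal signs therefore do not tell how far the shRNAs agree. Genes are not independent replicates.

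In the direct comparison of both shRNAs Gja5 was higher with shRNA 1 by 5.49 ± 0.12 (62.8 against 0.925 CPM), as were Rcvrn (5.26 ± 0.14, with 1 read in the shRNA 2 libraries), Selplg (4.81 ± 0.08), Lpar1, a lysophosphatidic acid receptor (4.69 ± 0.12), and Cemip, a hyaluronan-degrading protein (4.67 ± 0.07). Higher with shRNA 2 were Ttbk1 (-5.23 ± 0.15), Atcay (-4.71 ± 0.14), Apc2 (-4.59 ± 0.15), Rsad2 (-4.53 ± 0.25), Alox5 (-4.23 ± 0.16) and the AP-1 gene Fosl1 (-3.97 ± 0.18).

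Sarcomere genes were higher with shRNA 1 than with shRNA 2 in 36 of 42 cases, by a median of 1.22 or 1.44 after scaling (38 up and 2 down after scaling, camera adjusted p = 1.5e-13, or 0.26 with an estimated correlation). Atrial genes were higher in 14 of 18 (16 up and 0 down after scaling, camera adjusted p = 6.0e-06, or 0.26 with an estimated correlation). Matrix genes were higher with shRNA 1 in 21 of 29 cases (22 up and 3 down after scaling, camera adjusted p = 2.1e-05, or 0.29 with an estimated correlation). So were targets of YAP and TGF-beta in 14 of 18 (15 up and 2 down after scaling, camera adjusted p = 0.00018, or 0.26 with an estimated correlation). Interferon-response genes were lower with shRNA 1 in 32 of 34 cases, with a median of -1.71 or -1.49 after scaling (1 up and 32 down after scaling, camera adjusted p = 2.8e-07, or 0.29 with an estimated correlation). Genes of the integrated stress response were lower with shRNA 1 in 17 of 18 cases (0 up and 17 down after scaling, camera adjusted p = 6.6e-06, or 0.28 with an estimated correlation). The p53 targets were lower in 15 of 18 (1 up and 14 down after scaling, camera adjusted p = 0.00099, or 0.26 with an estimated correlation). Cholesterol synthesis genes were lower in 19 of 22, with Sqle at -1.16 ± 0.06 (3 up and 18 down after scaling, camera adjusted p = 0.0034, or 0.39 with an estimated correlation). Mitochondrially encoded genes were lower with shRNA 1 in 11 of 13 cases, and cell cycle genes in 20 of 30, or 9 and 18 after scaling, but neither list passed camera (camera adjusted p = 0.082 and 0.084). The T antigen transgene was lower with shRNA 1 by 1.05 ± 0.10 (limma adjusted p = 1.2e-08).

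In limma 10120 genes differed between the shRNAs, 3467 higher and 6653 lower with shRNA 1, against a median of all genes of -0.25, or 4605 and 5100 after trimmed-mean scaling and 4730 and 4976 after median-of-ratios scaling. As deposited, 2857 differed by 2-fold or more. The libraries of both shRNAs lay apart for 10130 genes (81.1%, where chance gives 10%).

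Several of the largest differences between the shRNAs lay next to each other on chromosome 10, a region singled out after its values were seen. From 54126486 to 54512169 in Rnor_6.0 lie Gas7, Rcvrn, Glp2r, Dhrs7c, Usp43 and Cfap52. With shRNA 1 against ppluc Gas7 rose by 3.41 ± 0.10, Rcvrn by 5.24 ± 0.14, Glp2r, a receptor for glucagon-like peptide 2, by 2.72 ± 0.19 and Cfap52, a cilium protein, by 2.94 ± 0.14, while Dhrs7c (1.11 ± 0.13, but -1.36 against untransduced libraries) and Usp43 (0.57 ± 0.10) rose by less. With shRNA 2 Gas7 stood at 0.20 ± 0.10, turning to -0.27 after trimmed-mean scaling, Rcvrn at -0.02 ± 0.14 and Glp2r at -0.32 ± 0.19, none of which passed as deposited. Cfap52 rose by 0.56 ± 0.14 (limma adjusted p = 0.0014), or 0.21 after trimmed-mean scaling, which did not pass. Dhrs7c and Usp43 fell with shRNA 2, by 3.04 ± 0.13 and 1.28 ± 0.10. At lower coordinates the myosin heavy chain genes Myh3, Myh4 and Myh8 fell with both shRNAs (-1.17, -1.74 and -2.58 with shRNA 1, and -3.25, -3.21 and -3.43 with shRNA 2). The map of the region shows each gene at its position.

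**Figure D2:**
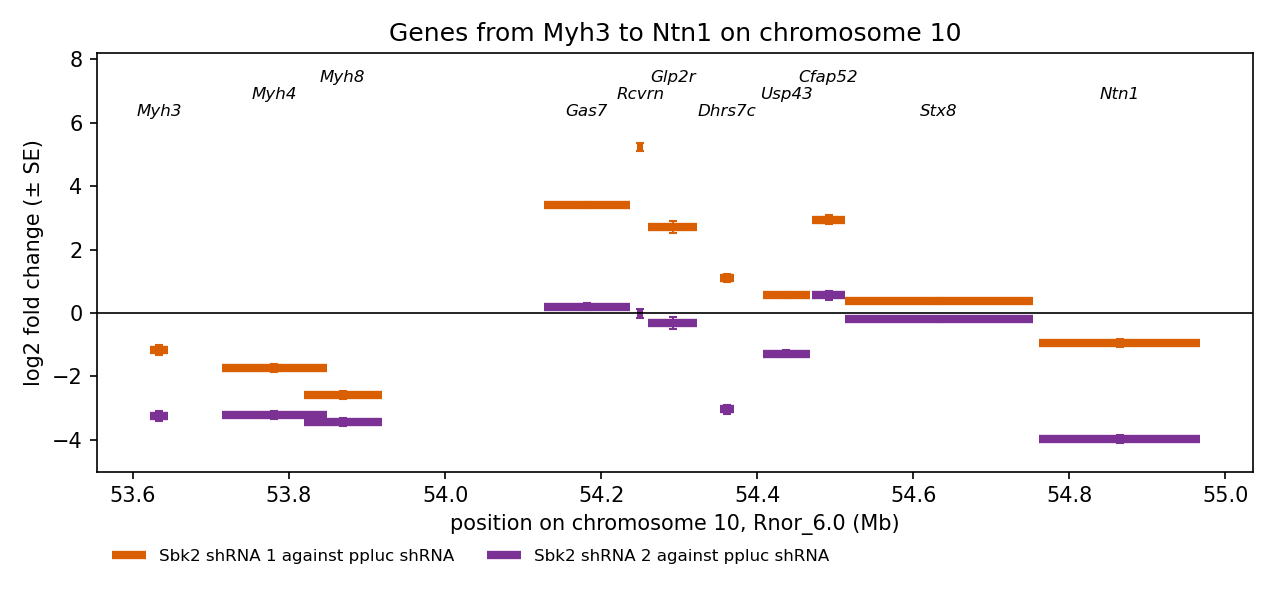
Log2 fold change of 11 genes between Myh3 and Ntn1 against their position on chromosome 10 in Rnor_6.0, in megabases, for shRNA 1 (orange) and shRNA 2 (purple) against ppluc. Thick bars span each gene and thin bars are the limma standard error. Gas7, Rcvrn, Glp2r and Cfap52 lie between 2.72 and 5.24 with shRNA 1 and between -0.32 and 0.56 with shRNA 2, where Dhrs7c and Usp43 lie at -3.04 and -1.28.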

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

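All tests on explanations in this part were chosen after the result was seen.

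Some genes moved one way in all 3 libraries with shRNA 1 and the other way in all 3 with shRNA 2, both against ppluc, and the difference between the shRNAs was tested in limma. Higher with shRNA 1 by log2 differences of 5.49, 4.69, 4.67, 4.64, 4.53, 4.15 and 4.08 were Gja5, the connexin 40 gene of atrial conduction, Lpar1, Cemip, the matrix protease gene Adamts15, Ampd3, an AMP deaminase gene, Dhrs7c and the sodium-proton exchanger gene Slc9a3. Gja5 went from 19.8 CPM with ppluc to 62.8 with shRNA 1 and 0.925 with shRNA 2, and Cemip from 404 to 839 and 32.6 CPM. Higher with shRNA 2 were Apc2 (-4.59), the histone gene Hist1h2bq (-4.03), Mthfd2 (-2.96) and Slc6a9, a glycine transporter gene (-2.92). Mthfd2 and Slc6a9 stood at 11.4 and 5.15 CPM with shRNA 1 and at 92.4 and 42.1 CPM with shRNA 2. Hist1h2bq has near-identical relatives, and how shared reads were counted is not given in the sources used here. Against untransduced libraries 6 of these 11 genes moved in opposite directions and passed with both shRNAs. Dhrs7c fell with both, Mthfd2 and Slc6a9 rose with both, and Ampd3 and Hist1h2bq did not pass with shRNA 1.

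Interferon-response genes rose with shRNA 2 (camera adjusted p = 3.5e-06, or 0.21 with an estimated correlation). With shRNA 1, where Sbk2 fell by nearly as much, 17 rose and 5 fell of 34 as deposited, which passed fry (adjusted p = 0.0079) and not camera (camera adjusted p = 0.95), and 11 rose and 12 fell after trimmed-mean scaling. The difference between the shRNAs passed camera but not with an estimated correlation (adjusted p = 0.29). Cxcl10 stood at 3.72 ± 0.11 and Tap1 at 1.87 ± 0.05 with shRNA 2. More vector with shRNA 2 was argued against by eGFP, which was higher with shRNA 1 by 0.43 ± 0.10. Loss of Sbk2 in proportion to its level was argued against by the list median with shRNA 1, 0.140 of that with shRNA 2 as deposited, -0.0191 after trimmed-mean and -0.0148 after median-of-ratios scaling. These ratios come from the same medians that showed the difference, so they are no independent evidence. An effect of shRNA 2 on other targets, a threshold in the response to Sbk2 and a difference between the cell batches that received each vector stay open and were not tested. The T antigen and the WHVPRE element (-0.99 ± 0.11 for shRNA 1 minus shRNA 2), both higher with shRNA 2, may mark such a difference between cells. The end of the T antigen vector did not pass, and these libraries cannot show such a difference.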

How the results depend on the processing

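The voom weights, the array weights, the untransduced control for single genes and both other treatments of features with several triples were chosen after seeing the data, and every other alternative before. In the 5 comparisons and for the overlap of both shRNAs, the count of changed genes stayed within 1.5 times its value under every alternative but 1. With a log2 fold change of at least 1 in addition, 2143 genes passed for both shRNAs, 1421 for shRNA 1, 4077 for shRNA 2, 2857 between the shRNAs, 533 for the control vector and 833 in the overlap, because that threshold leaves out smaller changes. Against untransduced libraries, 10343 genes passed for both shRNAs.

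Camera with an estimated correlation called 0 lists in each of the 5 comparisons, and fry called 30 between the shRNAs and 21 for the control vector, where camera called 15 and 10. An estimated correlation widens the spread allowed to a list whose members move together between libraries, and fry tests a list without reference to the other genes. From TPM, Sbk2 changed by -4.12. The cause was not tested.

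Leaving out 1 library in turn gave 10043 to 10540 genes for both shRNAs, 8727 to 8809 for shRNA 1, 10522 to 10772 for shRNA 2, 9725 to 10188 between the shRNAs, 6460 to 6611 for the control vector and 6035 to 6474 in the overlap. The lists called by camera numbered 21 to 22, 14 to 16, 23 to 24, 14 to 16 and 10 to 11 in the same order, and Sbk2 changed by -4.40 to -4.28.

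The text names 171 log2 changes of genes. Of 3718 alternatives 3701 were counted as the same, 5 no longer passed, 5 newly passed and 7 reversed. Being the same means the same direction on the same side of the threshold. For TPM group means, which are among the alternatives and carry no test, it means the same direction alone. The reversed ones included Gas7 with shRNA 2, which had not passed, at -0.27 after trimmed-mean and -0.28 after median-of-ratios scaling, since both take out the shift of all genes. Against untransduced libraries in place of ppluc, reversals were seen for the mean change of Tmsb4x (-0.42) and Flt1 (0.13, not passing), Dhrs7c with shRNA 1 (-1.36), and Gas7 and Rcvrn with shRNA 2 (-0.18 and 0.0038, passing in neither case). The control vector itself had moved Tmsb4x, Flt1 and Dhrs7c, and Rcvrn was near 0 against either control. There the mean change of Cnn1 and that of Aldh1l2 with shRNA 1 no longer passed, Glp2r with shRNA 2 newly passed, and Csrp3 with shRNA 1 changed by -0.22. Cfap52 with shRNA 2 no longer passed under either scaling. The difference in Sbk2 between the shRNAs, 0.67 with voom weights, did not pass there. Gas7 and Glp2r with shRNA 2 passed when the second ppluc or second shRNA 2 library (Gas7, 0.27 and 0.27) or the first ppluc library (Glp2r, -0.49) was left out. Depth limits Sbk1, with 0 to 3 reads per library, and the level of Sbk2 with either shRNA, which rests on 20 to 46 reads. No paired analysis was possible because the titles number the samples of each group from 1 to 3 while the deposited columns carry no such numbers, so the replicate block was not run. The edgeR and DESeq2 tests were not run because the deposited columns are averages and not reads of single libraries, and voom weights on the recovered reads were tried instead. The TPM table was not used as input of the tests, since it keeps no reads from which libraries were recovered.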

Other observations

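The tests on more genes being higher than lower were fixed before their result was seen, and the tests of splits and of neighbouring genes were chosen after it.

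Neighbouring genes on chromosome 10 rose together with shRNA 1. The run of Gas7, Rcvrn, Glp2r, Dhrs7c and Usp43, from 54126486 to 54467956, had a mean 2.35 above the median of all genes, and chance placing of changed genes was argued against by 0 of 1000 shuffles with a run as high (highest 1.92). A single library was argued against by 6 of the 6 tested genes from Gas7 to Cfap52, whose lowest shRNA 1 library lay above the highest of ppluc. For 5 of them it lay above all other 9, since Dhrs7c was higher in untransduced cells. The rule that named Gas7 and Rcvrn required libraries that did not overlap. The libraries of both groups lay apart, in either direction, for 76.6% of all genes, so the count of 6 does not set this region apart. With shRNA 2 a run on chromosome 7, from 101108189 to 102869860, with Fam84b (4.18 ± 0.14), Myc (4.62 ± 0.15) and Pvt1 (1.30 ± 0.07), had a mean 2.99 above the median, with 0 of 1000 shuffles as high (highest 2.63). The 3 genes also rose with shRNA 1, by 1.13 ± 0.14, 1.32 ± 0.15 and 0.52 ± 0.07, so their rise does not belong to shRNA 2 alone. These runs may reflect a vector inserted near them in a cell that gave rise to many others, a copy number change or shared regulation, none of which was tested, since no DNA reads are held. An insertion of this kind would need many divisions after the shRNA vector was added, which was shortly after differentiation had begun.

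More genes were called higher than lower with the Sbk2 shRNAs, and the median of all genes rose by 0.37. The 50 most abundant features held 21.3% of reads with ppluc, 16.2% with shRNA 1 and 12.5% with shRNA 2. Without them in the totals the median was 0.26, which argues against a few abundant genes taking fewer of the reads as the whole cause and leaves them as a part. Among 8887 genes of at least 10 CPM it was 0.32, which argues against low genes as the cause. Whether transcripts rose per cell cannot be read from these values, since CPM gives shares of a library.

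In a fit of 2 groups, 5515 genes changed between the 6 Sbk2 shRNA libraries and the 3 of ppluc. Of the 84 splits, 2 gave as many, the real one included. These splits cannot exclude chance differences between single cultures, since the labels do not say whether a group's libraries came from separate ones. The highest other split gave 8021 genes and parted the 3 shRNA 2 libraries from the rest, which points to a structure of the samples, the difference between the shRNAs, so the count does not single out this grouping. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real and highest other counts were 9373 and 1 for shRNA 1, 10560 and 0 for shRNA 2, 9908 and 1 between the shRNAs, and 7440 and 0 for the control vector, each reached by 1 split, the real one.

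The T antigen and the WHVPRE element were chosen for print after their values were seen. Their values are as deposited, where the median log2 change of all genes with shRNA 2 against ppluc was 0.50. In untransduced, ppluc, shRNA 1 and shRNA 2 cells they stood at 12.1, 8.45, 9.08 and 19.2 CPM for the T antigen and 6.08, 4.96, 4.73 and 9.99 CPM for the WHVPRE element, which was higher with shRNA 2 than with ppluc by 0.94 ± 0.11 (limma adjusted p = 3.1e-07). Other parts of the vectors did not pass with shRNA 2, TetR-KRAB at 0.26 ± 0.19 and the end of the T antigen vector at 0.30 ± 0.24 (limma adjusted p = 0.21 and 0.24), and the EMCV IRES, at 0.201 to 0.419 CPM, was not tested.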
